A study of Mus musculus with 6 samples.

How the data were processed

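Early T cell progenitors were sorted from fetal thymus, and 6 libraries were sequenced, 3 from wild-type control mice and 3 from mice with both E2A and HEB deleted. Per the labels' protocols, total RNA was isolated from sorted cells with a micro-scale column kit, turned into cDNA and amplified with a low-input SMARTer kit, sonicated, made into libraries with a low-input kit and sequenced on an Illumina HiSeq. Amplification from few cells makes reads dependent on each other, so depth overstates the number of molecules behind a value, and floors cover counting error only. Samples were placed in groups by their labels.

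The submitters' processing notes list bcl2fastq 1.8.4, TopHat2 2.0.14, DESeq version 2 and genome build mm9, without saying which step used which. The gene counter and the gene annotation are not given in the sources used here. One series-level table was used, and per the file headers it holds the authors' comparison of the groups. Its signal columns are, per the file headers, the authors' mean normalised count of each group. Its fold column is a ratio, the dKO mean over the control mean, as deposited, with a largest relative gap of 1.12e-07 to the ratio recomputed from the means. Its p-value and adjusted p-value columns are the authors' own as deposited. Redoing the Benjamini-Hochberg adjustment on the deposited p-values gave the deposited adjusted values within 4.08e-07. The log2 column was not used, since 729 of its cells hold a spreadsheet error, in each case for a gene at 0 in dKO, and log2 changes were computed from the means. The table has 22609 rows, of which 6368 are at 0 in both groups without a p-value and 16241 were tested. Of the tested genes, 787 were listed at 0 in control and 729 at 0 in dKO. A spreadsheet had turned 25 gene names into dates, 8 of them called, and these stayed in the counts of genes and out of the lists.

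A design with a count test on values per library had been fixed before the data were examined, with the authors' own test as the choice for a table of group means. The table holds group means only, so no new test per gene was made outside the closing section: a gene was called higher or lower in dKO at the authors' adjusted p under 0.05. A group at 0 was set to a floor of 3 reads over the group, a mean of 1.21 in control and 0.963 in dKO, and the fold is then a lower bound. Named genes were fixed by rule before the data were examined: the E and Id genes, the 10 largest changes in each direction among called genes with a mean of at least 100 (predicted gene models left out), and per list up to 4 called members with the smallest adjusted p and the 3 most abundant that did not pass. Other members could be named where a count was 5 or fewer. Genes named outside this rule were chosen after their values were seen: Il7r and, in the closing observations, Gt(ROSA)26Sor, Mx2, Ifi44 and Gbp3. Some genes that the rule takes are not reported here.

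Of 41 lists fixed before the data were examined, 38 were tested. The patterns for T cell receptor and immunoglobulin loci matched only Tradd and Ighmbp2, which are not such loci, and that for mitochondrially encoded genes matched none. In 4 places a symbol was matched through a synonym (Gpr44, Sfpi1 for both of its lists, and Beta-s). For each list the shares called higher and lower were compared with all other tested genes by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over 76 tests. The median log2 change was set against 10000 random lists of the same size matched on mean expression, with adjustment over the 38 lists. As an alternative a rank test with a preset correlation of 0.01 was run (cameraPR of limma 3.58.1 in R 4.3.3). The same test on z values from the authors' p-values, signed by direction and not ranked, was added after the data were examined. An estimated correlation needs values per library and was not run. Genes of a list are not independent, and several lists share members. Both tests were tried on shuffled data for the comparison of dKO with control over 15447 genes. With folds shuffled among genes of like abundance, the median test gave p under 0.05 in 6% of 200 unchanged lists. It did so in 100% of lists shifted by 1 on the log2 scale. With calls shuffled over all genes, Fisher's test gave p under 0.05 in 5% of unchanged lists. That shuffle removes any link between abundance and calls, so it cannot show how Fisher's test treats lists of abundant genes. Fisher's test was not matched on abundance. Of genes with a mean under 10, 1.26% were called, against 43.9% with a mean of at least 1000.

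After the data were examined, the group means were found to be sums of whole reads, each weighted by its library. All 5259 control values and all 5361 dKO values up to 100 had a unique solution in whole reads, against 0.0427% and 0.0217% of random values. Between 100 and 500, 18.7% of control and 77.6% of dKO values had one. On simulated data 100% of the solutions found up to a mean of 100 were right. The solved size factors were 1.02, 0.952 and 0.823 for control and 1.16, 1.08 and 1.04 for dKO, and their products with the sums give the approximate depth. The libraries so recovered carry no replicate number. Reads were recovered in both groups for 6481 genes, mostly of low abundance, so a count test over all genes was not possible. For the 156 called genes of the lists and of the text with reads recovered in a group, the fold was recomputed without each such library, a step added after the data were examined. It moved by over 1.5 times in 35 genes and turned direction in 0. These genes had already passed a test that weighs the spread between libraries, so few turns could be expected. Leaving out a library above the mean of the lower group can only raise the fold. Reads of a group with a mean above 500 were not recovered, so its libraries could not be left out. The step therefore does not show that the folds are free of single libraries. Where such a gene is named, the fold without the library is given, or the group mean where that mean is 0 or under the floor. For the closing section alone, limma (trend) was run on log2(normalised count + 1) over 3136 of these genes with a mean of at least 10. On simulated data of 3136 genes, with 200 changed 4-fold, it found 85% of the changed genes with 3.95% false calls.

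Neighbouring genes were taken from the order of genes in a RefSeq table of assembly GRCm38, used only for which genes lie next to each other; 16095 tested genes were matched and 146 were not. No coordinates are given. Alternatives were other thresholds, a minimum fold change, other minimum means, centring on the median, the mean in place of the median and the rank test. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.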

Results

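RNA sequencing was carried out on early T cell progenitors sorted from the fetal thymus of C57BL/6 mice, the most immature thymocyte stage, taken as lineage-negative cells with CD44 and c-Kit and without CD25, CD4 or CD8. There were 3 wild-type control libraries and 3 libraries from mice lacking E2A (the product of Tcf3) and HEB (the product of Tcf12), deleted with a Cre recombinase expressed from the Il7r locus. E2A and HEB are E proteins, basic helix-loop-helix transcription factors of lymphoid development, and Id proteins are their antagonists. The double-knockout (dKO) cells were additionally sorted for YFP and the control cells were not, so the gate differed between the groups along with the genotype. The series concerns the choice of lymphoid progenitors between adaptive and innate fates under control of E and Id proteins, and its single comparison is dKO against control. The values came from the authors' deposited table, which gives 1 mean normalised count per gene and group, a fold change, a p-value and an adjusted p-value, and no value per library. The normalised counts summed to 22.1 M in the control group and 23.4 M in the dKO group in the authors' deposited table. The spacing of the low means put the depth at about 18.2 to 22.6 M reads per control library and 24.3 to 27.0 M per dKO library. Reads per library could be recovered from the means for genes of low abundance, and libraries are named below by their size factors. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

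Both targeted genes were lower in the dKO group. Tcf3 went from a mean of 8931 in control to 364 in dKO in the authors' deposited table, 24.6-fold lower or 4.07% of control (authors' adjusted p = 1.2e-292). Tcf12 went from 3845 to 562 in the authors' deposited table, 6.84-fold lower (authors' adjusted p = 1.49e-97). The labels do not say which exons were removed, so transcripts without them may still have been counted. The third E protein gene, Tcf4, was also lower, by 1.69-fold, in the authors' deposited table. The Id genes moved in both directions. In the authors' deposited table Id2, the Id gene of innate lymphoid cells, rose 3.55-fold from 3583 to 12733 and Id3 rose 2.51-fold from 46.3 to 116, whereas Id1 fell 3.0-fold from 131 to 43.8. Id4 was listed at 0 in both groups of the authors' deposited table. Of the 6 measured E and Id genes, 2 rose and 4 fell, and Tcf3 and Tcf12, the deleted genes, are among those that fell. The list's adjusted p of 0.0137 for the share that fell (Fisher's exact test) and median of -1.17 (adjusted p = 0.207 with the rank test) therefore rest partly on the deletion itself.

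The difference between the groups was broad. At the authors' adjusted p under 0.05, 4707 of 16241 tested genes (29.0%) differed, 2460 higher and 2247 lower in dKO. Of these, 2039 differed at least 2-fold, 1114 higher and 925 lower, and 137 were at least 10-fold higher and 135 at least 10-fold lower. Among named genes with a mean of at least 100, the largest falls in the authors' deposited table were those of Ptcra, the pre-T cell receptor alpha chain, 609-fold lower from 924 to 1.52, and of Ly6d, a surface marker of lymphoid commitment, 290-fold lower from 688 to 2.37. The authors' deposited table also had Mpzl2 266-fold, Thbd 185-fold, Lrrc32 173-fold, Esm1 112-fold, Beta-s (an adult beta globin) 83.6-fold and Rag1 61.0-fold lower. Some of these falls were deeper without a single dKO library. Without that of size factor 1.16 Ly6d was 493-fold, Thbd 315-fold and Beta-s 306-fold lower. Without that of size factor 1.04 Mpzl2 was 670-fold and Rag1 109-fold lower. In each case the library left out lay above the dKO mean of that gene, so leaving it out could only deepen the fall. The dKO reads of Esm1 and of Lrrc32 all lay in the library of size factor 1.08, and without it the dKO mean of each was 0. The dKO means of Ptcra, 1.52, and of Lrrc32, 1.24, were close to the floor of 0.963. Their folds therefore rest on few reads. Slc16a5 was listed at 0 in dKO and was at least 211-fold lower against a control mean of 203 in the authors' deposited table, with a floor of 3 reads over the group. The largest rises in the authors' deposited table were those of Hapln3, 94.0-fold to 395, Trpm6, 66.7-fold, Rln3, 60.3-fold, and Abi3bp, 56.9-fold. Ncr1, the activating receptor NKp46 of NK cells and some innate lymphoid cells, rose 42.3-fold from 5.47 to 231 in the authors' deposited table. Gpr15 (34.3-fold), Xdh (32.9-fold), Fam19a3 (31.3-fold), the costimulatory receptor gene Tnfrsf9 (20.7-fold, from 386 to 7991) and the cytokine gene Lif (19.9-fold, from 208 to 4134) completed the 10 largest rises in the authors' deposited table. The control reads of Hapln3 all lay in the library of size factor 0.952, and without it the control mean was 0. Without the same library Ncr1 was 95.3-fold and Fam19a3 50.8-fold higher. Trpm6 was 135-fold higher without the control library of size factor 0.823. Genes of low abundance were seldom called: 1.26% of those with a mean under 10 passed, against 43.9% of those with a mean of at least 1000.

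**Figure D1:**
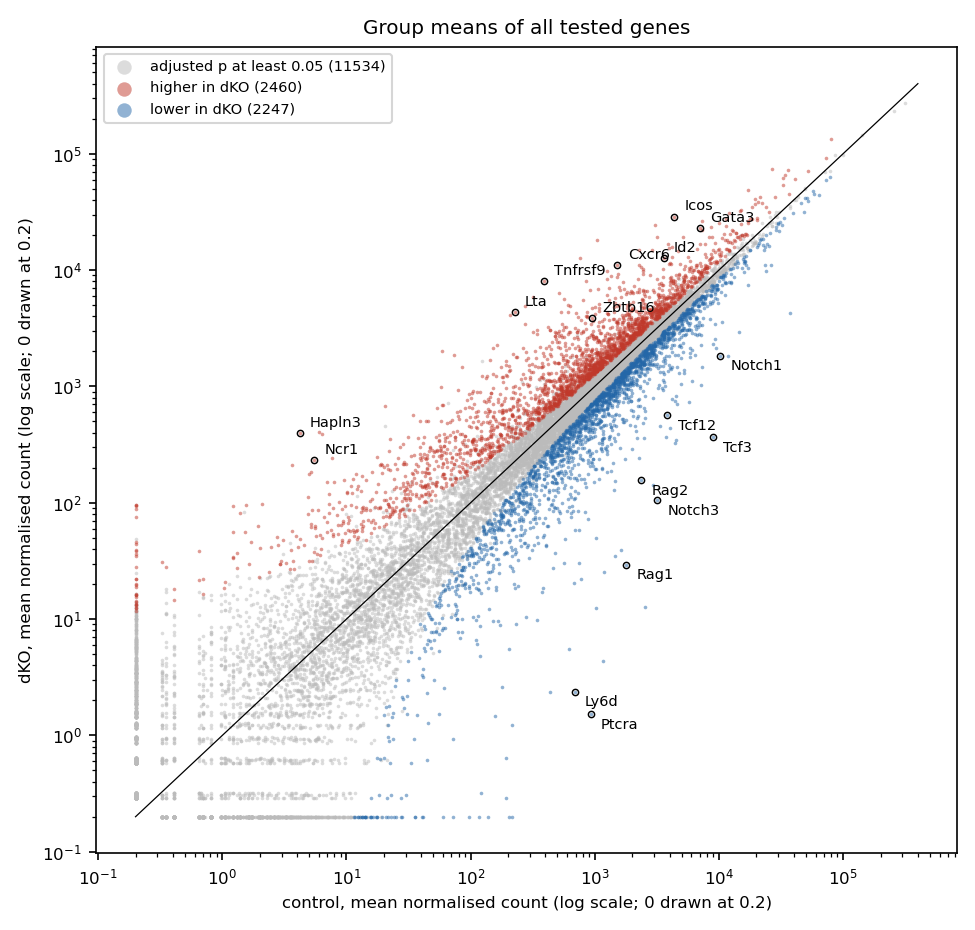
Mean normalised count of each tested gene in control (x axis) and dKO (y axis), both on log scales, with means of 0 drawn at 0.2. The 2460 genes higher in dKO are red, the 2247 lower are blue and the others grey. Ptcra, Ly6d and Rag1 lie far below the line of equality and Hapln3 and Ncr1 far above it.

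The lists for the Notch pathway, receptor gene recombination and later thymocytes each held a larger share of falling genes than the other tested genes. Of 15 Notch receptors and targets, 7 fell, 2 rose and 6 did not pass (8 fell adjusted over the list alone; Fisher's exact test for the share that fell, adjusted p = 0.00737). In the authors' deposited table Notch3 fell 30.2-fold from 3163 to 105, Notch1 5.56-fold from 10176 to 1829 and Myc 2.70-fold from 9311 to 3451. Hey1 rose 11.8-fold from 79.3 to 934 and Notch2 2.37-fold from 289 to 685 in the authors' deposited table. Il2ra, which encodes CD25, had means of 8417 and 8536 in the authors' deposited table and did not pass. Both groups were sorted as cells without CD25, which may limit a difference in this gene. The median log2 change of the Notch list was -0.69 (adjusted p = 0.000507 against random lists, 0.0537 with the rank test). Of 12 V(D)J recombination genes, 5 fell, 1 rose and 6 did not pass (Fisher's exact test for the share that fell, adjusted p = 0.0450). Besides Rag1, the authors' deposited table had Rag2 15.1-fold lower, from 2363 to 157, and Xrcc6, which encodes the end-joining protein Ku70, 3.02-fold lower. Hmgb2 rose 1.51-fold in the authors' deposited table. The median of the recombination list, -0.33, did not stand apart from random lists (adjusted p = 0.0632). Of 18 genes of double positive thymocytes, 8 fell, 2 rose and 8 did not pass (9 fell adjusted over the list alone; Fisher's exact test for the share that fell, adjusted p = 0.00575), and their median was -1.11 (adjusted p = 0.000507, 0.0664 with the rank test). Arpp21 fell 20.5-fold from 2928 to 143 and Aqp11 12.2-fold from 885 to 72.4 in the authors' deposited table. The double positive list includes Cd4, Cd8a and Cd8b1, whose products the gate excluded in both groups. It also shares the falling genes Rag1 and Rag2 with the recombination list and Ptcra with the Notch list.

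T cell signalling and transcription factor genes moved in both directions. Of 25 genes of the pre-T cell receptor, CD3 and receptor signalling, 9 rose, 10 fell and 6 did not pass (10 rose adjusted over the list alone; Fisher's exact test, adjusted p = 0.0247 for the share that rose and 0.00477 for the share that fell). The kinase gene Txk rose 5.33-fold in the authors' deposited table, against the falls of Ptcra and Ly6d. The median of this list was 0.23 and its mean -0.29 on the log2 scale, with opposite signs, and neither test set it apart (adjusted p = 0.101 against random lists, 0.854 with the rank test). Of 19 T lineage transcription factors, 10 rose, 6 fell and 3 did not pass (Fisher's exact test for the share that rose, adjusted p = 0.000733). In the authors' deposited table Gata3, a factor of T cells and of type 2 innate lymphoid cells, rose 3.26-fold from 7051 to 22961, Ikzf3 rose 4.83-fold and Tox 2.62-fold, while Myb fell 4.93-fold from 14608 to 2962. Bcl11b, a T commitment factor, had means of 4649 and 7548 in the authors' deposited table and did not pass (authors' adjusted p = 0.135). The median of this list was 0.39 (adjusted p = 0.0258 against random lists, 0.118 with the rank test). Of 12 gamma delta T cell genes, 5 rose, 4 fell and 3 did not pass, with a median of 0.22 (adjusted p = 0.288). Maf rose 5.32-fold and Sox13 fell 2.75-fold in the authors' deposited table.

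The lymphoid priming and B lineage lists also held a larger share of falling genes than the other tested genes. They share falling members with each other and with the lists above, so they are not separate evidence. Rag1 and Ly6d are in both lists. Rag1 and Rag2 are also in the recombination list, and Notch1 is in the Notch list. Of 18 lymphoid priming genes, 8 fell, 6 rose and 4 did not pass (Fisher's exact test for the share that fell, adjusted p = 0.00575). Rag2, Notch1 and Ly6d were among the members that fell. Il2rg, the common cytokine receptor chain, rose 2.75-fold from 8595 to 23652 and Il7r 1.22-fold from 3235 to 3959 in the authors' deposited table. The Cre recombinase of the dKO mice is expressed from the Il7r locus, so reads of Il7r may include those of an altered allele. The median of the priming list was -0.43 (adjusted p = 0.0016, 0.432 with the rank test). Of 22 B lineage genes, 8 fell, 3 rose and 11 did not pass (Fisher's exact test for the share that fell, adjusted p = 0.0212), with a median of -1.43 (adjusted p = 0.000507). Members of low abundance that did not pass also enter this median. The most abundant that did not pass were Cd79b, with means of 1143 and 1041, Bank1, 105 and 162, and Pou2af1, 55.8 and 23.0, in the authors' deposited table. Members that fell in the authors' deposited table included Bst1, 108-fold from 159 to 1.47, and Cd24a, 2.16-fold. Foxo1 (3.39-fold), Cd22 (8.01-fold) and Lef1 (from 825 to 1235) were the B lineage members that rose in the authors' deposited table. Without the dKO library of size factor 1.16 the dKO mean of Bst1 was 0.482, under the floor of 0.963. Without the control library of size factor 0.952 the control mean of Cd22 was 1.095, under the floor of 1.21.

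Genes of innate lymphoid cell (ILC) progenitors rose nearly as a whole. Of 19 measured, 17 rose, 1 fell and 1 did not pass (2 fell adjusted over the list alone; Fisher's exact test for the share that rose, adjusted p = 3.54e-11), and the median log2 change was 1.83 (adjusted p = 0.000507). In the authors' deposited table Cxcr6 rose 7.29-fold from 1521 to 11082, Il18r1 7.80-fold from 418 to 3265 and Pdcd1 from 568 to 5682. Zbtb16, which encodes PLZF, a factor of ILC precursors, rose 4.06-fold from 950 to 3860 in the authors' deposited table. The member that fell was Tcf7, 1.28-fold from 10825 to 8433, and Itga4, with means of 20025 and 17503, did not pass in the authors' deposited table. Of 32 genes of type 2 ILCs (ILC2), 20 rose, 2 fell and 10 did not pass (Fisher's exact test for the share that rose, adjusted p = 2.04e-08), with a median of 1.96 (adjusted p = 0.000507). Icos rose 6.60-fold from 4367 to 28812, Ccr8 7.39-fold from 914 to 6757 and Arg1 14.2-fold from 151 to 2137 in the authors' deposited table. Il4ra (3.32-fold) and Gfi1 (2.65-fold) fell in the authors' deposited table. Il1rl1, the IL-33 receptor, had means of 866 and 1217 in the authors' deposited table and did not pass.

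The lists for other innate lymphocytes also held a larger share of rising genes than the other tested genes, with members that fell. Of 36 genes of NK cells and ILC1, 25 rose, 6 fell and 5 did not pass (Fisher's exact test for the share that rose, adjusted p = 1.19e-11), with a median of 1.68 (adjusted p = 0.000507). Cd226 rose 8.48-fold and Ikzf2 2.50-fold in the authors' deposited table. Fasl fell 6.49-fold from 986 to 152 in the authors' deposited table, where Klrb1b had means of 192 and 0.642. The dKO reads of Klrb1b all lay in the library of size factor 1.04, and without it the dKO mean was 0. Of 25 genes of lymphoid tissue inducer cells and ILC3, 12 rose, 7 fell and 6 did not pass (Fisher's exact test for the share that rose, adjusted p = 0.00058). The lymphotoxin genes Lta and Ltb rose 19.2-fold from 226 to 4337 and 4.07-fold from 1704 to 6937 in the authors' deposited table, and Cd93 fell 5.04-fold. The median of this list was 0.81 (adjusted p = 0.000507, 0.128 with the rank test). The lists shared few rising genes: 13 of the 17 that rose in the ILC progenitor list, 16 of 20 in the ILC2 list, 8 of 12 in the ILC3 list and 24 of 25 in the NK list were in no other of these lists. Of 19 members of the NK receptor gene families, 9 rose, 2 fell and 8 did not pass (Fisher's exact test for the share that rose, adjusted p = 0.00402). Klrg1 rose 11.3-fold and Klrd1 3.20-fold, and Klrb1f fell 3.74-fold, in the authors' deposited table. Their median was 2.24 (adjusted p = 0.000507, 0.0612 with the rank test), and the family pattern also took in Klraq1, which is not an NK receptor. Of 6 granzymes, Gzmb (5.99-fold, from 1531 to 9173) and Gzmc (7.69-fold) rose and Gzma fell 2.81-fold from 3601 to 1283 in the authors' deposited table. The other 3 did not pass, and the median of -0.13 and mean of 0.49 differed in sign (adjusted p = 0.815). Without the control library of size factor 0.823 Klrg1 was 17.0-fold and Gzmc 13.2-fold higher.

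**Figure D2:**
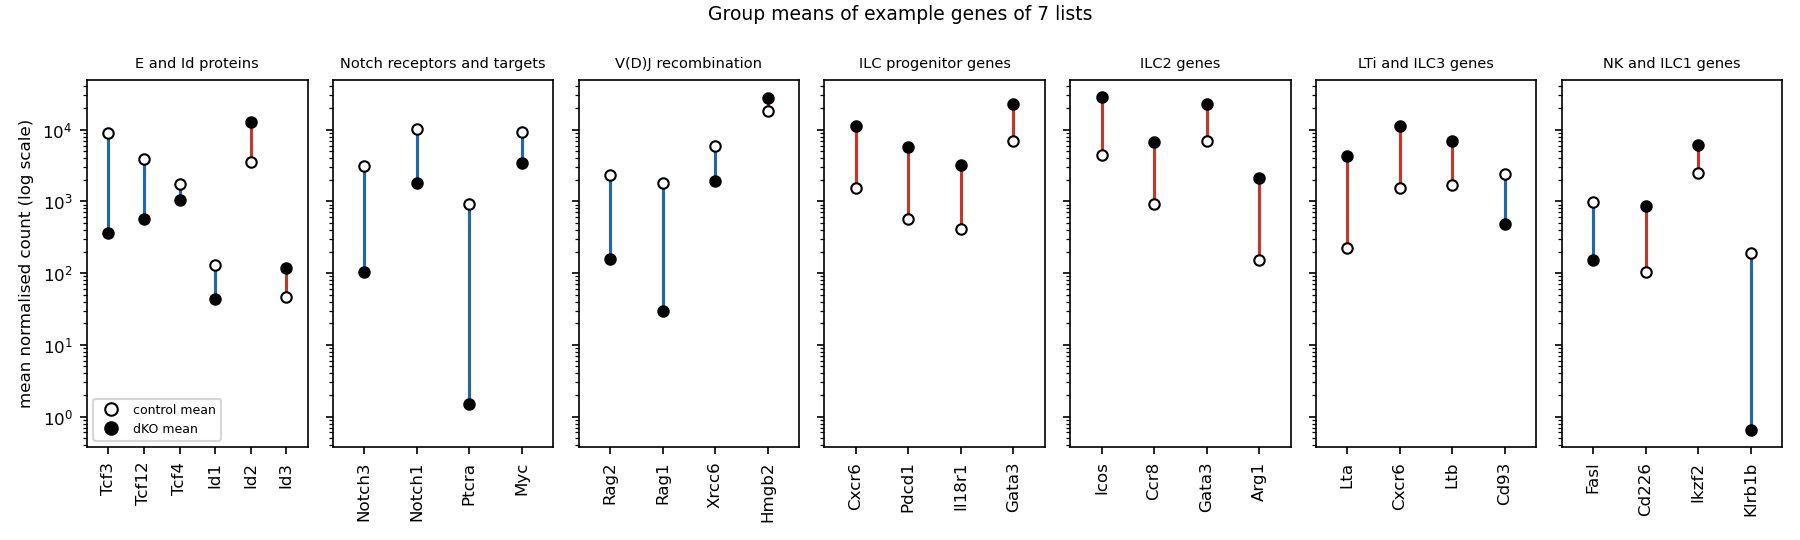
Mean normalised count (log scale) in control (open circles) and dKO (filled circles) for the E and Id genes and for up to 4 genes with the smallest adjusted p in each of 6 lists; each point is the authors' mean of 3 libraries, with no error given. Red lines join genes higher in dKO and blue lines genes lower in dKO: Notch3, Notch1 and Ptcra fell, and Icos, Ccr8, Cxcr6 and Lta rose.

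Secreted effectors and receptors for cytokines and chemokines held more rising than falling genes. Of 33 cytokines and secreted effectors, 18 rose, 2 fell and 13 did not pass (Fisher's exact test for the share that rose, adjusted p = 1.47e-06), with a median of 2.0 (adjusted p = 0.000507). Tnfsf14 rose 3.93-fold from 265 to 1040, while Gzma and Il16 (1.41-fold) fell, in the authors' deposited table. Of 39 cytokine receptors, 19 rose, 10 fell and 10 did not pass (Fisher's exact test for the share that rose, adjusted p = 6.1e-06). Il27ra rose 4.89-fold and Tgfbr2 2.53-fold in the authors' deposited table. The median of the receptor list was 0.41 (adjusted p = 0.000894, 0.0736 with the rank test). Of 41 chemokine receptors and adhesion genes, 25 rose, 6 fell and 10 did not pass (10 fell adjusted over the list alone; Fisher's exact test for the share that rose, adjusted p = 4.71e-10), with a median of 1.40 (adjusted p = 0.000507). In the authors' deposited table Itgb3 rose 8.0-fold from 3057 to 24453 and Ccr2 7.80-fold from 1249 to 9733. Of 26 integrins, 9 rose, 7 fell and 10 did not pass (Fisher's exact test for the share that rose, adjusted p = 0.0305). Itgae, an epithelial retention receptor, rose 6.06-fold from 3182 to 19279 and Itgb7 3.59-fold from 7303 to 26223 in the authors' deposited table. The integrin median of -0.12 and mean of 0.19 differed in sign (adjusted p = 0.486). Of 30 genes of the TNF and TNF receptor families, 7 rose, 1 fell and 22 did not pass (Fisher's exact test for the share that rose, adjusted p = 0.345), with a median of 0.57 (adjusted p = 0.00326). Tnfrsf25 rose 6.97-fold and Tnfrsf18 6.05-fold, and Tnfrsf8, listed at 0 in dKO, was at least 25.1-fold lower in the authors' deposited table. All 8 Gimap genes, small GTPases of lymphocytes, passed: Gimap3 (12.6-fold), Gimap4 (4.62-fold) and Gimap8 (2.58-fold) rose in the authors' deposited table, and the other 5 fell (Fisher's exact test for the share that fell, adjusted p = 0.00678). The Gimap median was -0.75 (adjusted p = 0.0106, 0.383 with the rank test) and the mean 0.28, with opposite signs. Gimap3 was 23.1-fold higher without the control library of size factor 1.02.

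Stem and progenitor genes were lower in dKO. Of 30 measured, 23 fell, 4 rose and 3 did not pass (24 fell adjusted over the list alone; Fisher's exact test for the share that fell, adjusted p = 9.16e-13), and the median log2 change was -1.69 (adjusted p = 0.000507). Nfe2 fell 5.91-fold from 4396 to 744 and Angpt1 5.39-fold from 4498 to 834 in the authors' deposited table. The members that rose in the authors' deposited table were Kit (1.35-fold, from 14094 to 19067), Meis1 (1.85-fold), Gata2 (1.98-fold) and Ly6a (4.63-fold). Both groups were sorted for c-Kit, the product of Kit. Of 11 Hox genes, Hoxa7 fell 5.20-fold and Hoxa9 3.41-fold in the authors' deposited table and 9 did not pass, with a median of -0.83 (adjusted p = 0.283). Of 29 granulocyte and monocyte genes, 7 fell, 4 rose and 18 did not pass (Fisher's exact test for the share that fell, adjusted p = 0.195). Mpo, the granule enzyme myeloperoxidase, fell 5.02-fold from 7310 to 1457 and Prtn3 7.35-fold from 321 to 43.7 in the authors' deposited table. The median of the list was -0.87 (adjusted p = 0.0038, 0.177 with the rank test).

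The gate took lineage-negative cells with CD44 and c-Kit and without CD25, CD4 or CD8, which should remove most mature dendritic, erythroid and stromal cells, whereas mast cells carry c-Kit; the antibodies of the lineage cocktail are not given in the sources used here. The dKO cells alone were also sorted for YFP, so such cells may have been removed to a different extent in each group. Whether they were was not tested. Markers of such cells moved in both directions. Of 19 mast cell and basophil genes, 10 rose, 4 fell and 5 did not pass (Fisher's exact test for the share that rose, adjusted p = 0.000733), with a median of 1.46 (adjusted p = 0.000894, 0.0659 with the set test on signed z). Il4 rose 7.30-fold from 71.1 to 519, Tpsb2 11.4-fold and Cd200r3 6.12-fold, while the protease gene Cpa3 fell 2.71-fold from 5824 to 2147, in the authors' deposited table. Tpsb2 was 17.7-fold higher without the control library of size factor 0.823. Of 22 dendritic cell genes, 5 rose, 6 fell and 11 did not pass (7 rose adjusted over the list alone), with a median of 0.13 (adjusted p = 0.446). Xcr1 rose 8.83-fold, Spib fell 25.5-fold from 232 to 9.08 and Plac8 fell 3.92-fold in the authors' deposited table. Of 9 MHC class II genes, H2-Oa rose 2.95-fold, H2-DMa fell 3.24-fold, 3 more fell and 4 did not pass in the authors' deposited table (3 rose adjusted over the list alone). Their median of -0.65 and mean of 0.19 differed in sign (adjusted p = 0.186). Of 17 erythroid and platelet genes, 4 fell, none rose and 13 did not pass at the authors' adjusted p (0 rose and 5 fell at an unadjusted p under 0.05), with a median of -0.51 (adjusted p = 0.101). They included Beta-s, Itga2b (2.54-fold, from 1481 to 583) and Gp9 (3.95-fold) in the authors' deposited table, where Vwf had means of 44.9 and 0.62. The Vwf control mean was 19.3 without the control library of size factor 0.823, and its dKO mean was 0 without the dKO library of size factor 1.08. Of 21 genes of thymic epithelium, stroma and endothelium, 1 rose, 2 fell and 18 did not pass, with a median of 0.18 (adjusted p = 0.446). Pdgfrb fell 4.38-fold from 9430 to 2152 and Pecam1 1.28-fold, and Kdr, listed at 0 in control, was at least 13.4-fold higher in the authors' deposited table. Kdr was at least 7.44-fold higher without the dKO library of size factor 1.04.

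Lists for proliferation, survival, metabolism and ribosomes had median log2 changes between -0.45 and 0.51. Of 44 cell cycle genes, 18 rose, 7 fell and 19 did not pass (20 rose and 8 fell adjusted over the list alone; Fisher's exact test for the share that rose, adjusted p = 0.000205), with a median of 0.23 (adjusted p = 0.031, a call that ended with the mean in place of the median). Rrm2, of nucleotide synthesis, rose 1.79-fold and the inhibitor gene Cdkn2c 3.92-fold, while Ccnd1 fell 4.40-fold and Cdk6 2.37-fold, in the authors' deposited table. Of 24 apoptosis genes, 10 rose, 3 fell and 11 did not pass (11 rose adjusted over the list alone; Fisher's exact test for the share that rose, adjusted p = 0.00575), with a median of 0.35 (adjusted p = 0.0292, 0.0923 with the set test on signed z). The survival genes Bcl2 (2.30-fold) and Bcl2l1 (1.71-fold) and the death gene Bik (8.44-fold) rose in the authors' deposited table. Of 21 glycolysis genes, 15 rose, 2 fell and 4 did not pass (16 rose and 3 fell adjusted over the list alone; Fisher's exact test for the share that rose, adjusted p = 1.16e-07), with a median of 0.51 (adjusted p = 0.00228). Pfkp rose 3.91-fold, Slc16a3, a lactate exporter, 6.01-fold and Aldoa 2.13-fold, and Pdk1 fell 1.85-fold, in the authors' deposited table. Of 18 cholesterol synthesis genes, 13 fell, 2 rose and 3 did not pass (14 fell adjusted over the list alone; Fisher's exact test for the share that fell, adjusted p = 2.72e-07), with a median of -0.45 (adjusted p = 0.000507). Sqle fell 1.73-fold and Fdps 1.63-fold, while Cyp51 (1.42-fold) and Mvd (1.44-fold) rose, in the authors' deposited table. Of 79 ribosomal protein genes, 18 fell, 1 rose and 60 did not pass (14 fell adjusted over the list alone), with a median of -0.21 (adjusted p = 0.000507). The share that rose was below that of other genes (Fisher's exact test, adjusted p = 0.000319), and Rps2 fell 1.28-fold from 57899 to 45315 in the authors' deposited table. Of 63 histone genes, 9 rose, 2 fell and 52 did not pass, a share of falls below that of other genes (Fisher's exact test, adjusted p = 0.0266), with a median of 0.14 (adjusted p = 0.221). Hist1h2ag rose 1.61-fold and Hist1h2bc fell 1.89-fold in the authors' deposited table.

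Interferon-stimulated genes and stress genes were higher in dKO. Of 28 interferon-stimulated genes, 18 rose, none fell and 10 did not pass (23 rose adjusted over the list alone, and 0 fell at an unadjusted p under 0.05; Fisher's exact test for the share that rose, adjusted p = 5.98e-08), with a median of 2.08 (adjusted p = 0.000507). Irf9 rose 3.13-fold from 963 to 3015 and the RNA sensor gene Ddx58 3.74-fold from 967 to 3613 in the authors' deposited table. Oasl2 had means of 724 and 2782 and did not pass (authors' adjusted p = 0.0768 in the authors' deposited table). Of 25 stress and immediate early genes, 13 rose, 3 fell and 9 did not pass (15 rose adjusted over the list alone; Fisher's exact test for the share that rose, adjusted p = 0.000128), with a median of 1.11 (adjusted p = 0.000507). Ddit4 rose 5.96-fold, Zfp36 3.68-fold and Egr1 7.68-fold from 160 to 1228 in the authors' deposited table. None of the 5 measured sex-linked genes passed the authors' test, and 0 had an unadjusted p under 0.05: Xist had means of 3169 and 4463, Ddx3y 1014 and 869 and Kdm5d 562 and 255 in the authors' deposited table. Their median was -0.95 (adjusted p = 0.0241, 0.531 with the rank test). Xist and the Y-linked gene Ddx3y were abundant in both groups, so each group held female and male cells. The share of each sex per library is not known.

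**Figure D3:**
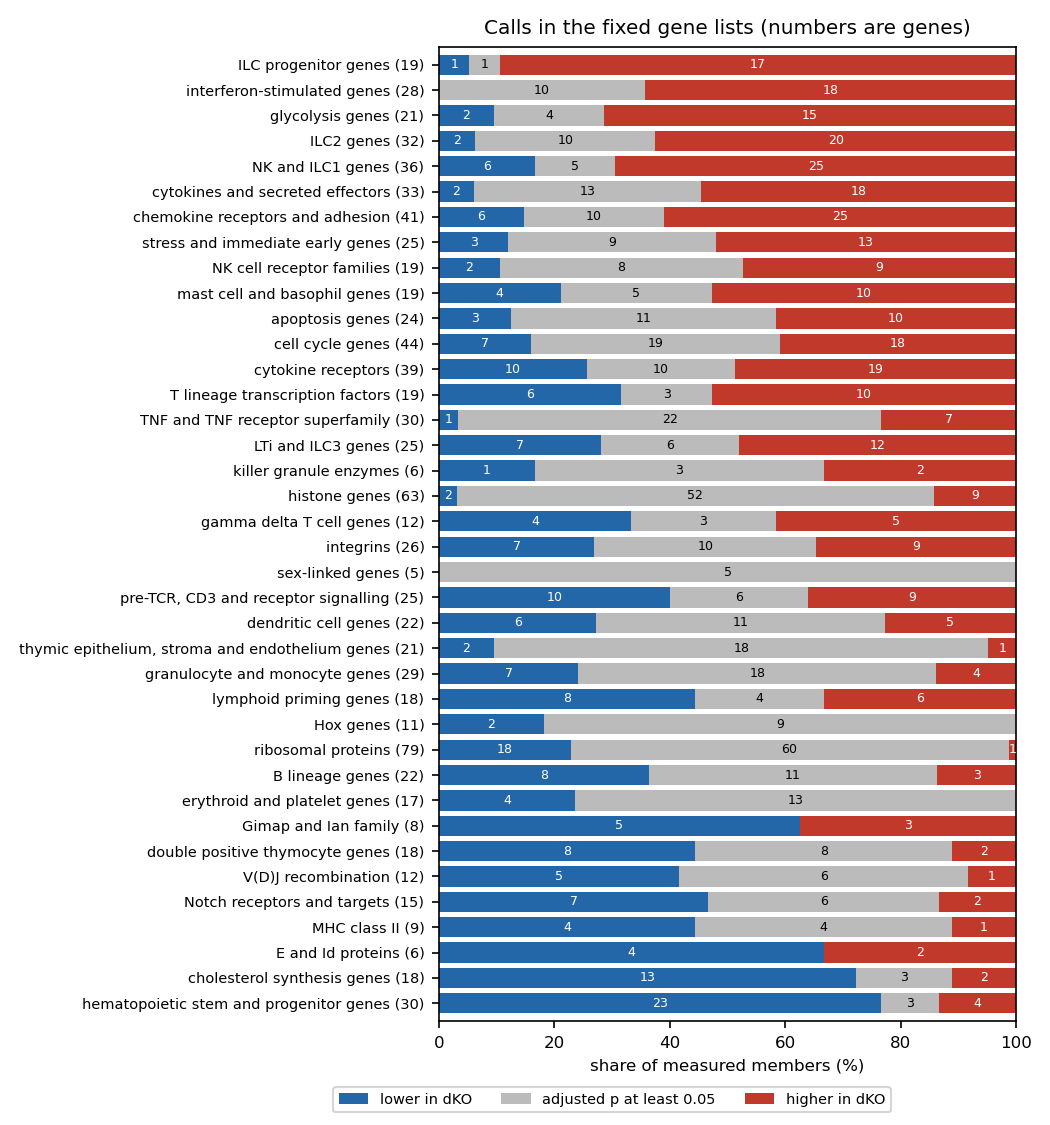
Share of measured members (x axis, percent) of each of 38 gene lists that were lower in dKO (blue), not past the authors' adjusted p of 0.05 (grey) or higher in dKO (red), ordered by the balance of rises and falls. Numbers in the bars are genes and those in brackets the measured members: 17 of 19 ILC progenitor genes rose and 23 of 30 stem and progenitor genes fell.

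Across the 38 tested lists, the share of rising genes was above that of other genes in 17 lists and the share of falling genes in 10, the E and Id list with its deleted genes included. Several lists share members, so these counts are not of independent results. Fisher's test was not matched on abundance, and abundant genes were called more often. The median change stood apart from random lists of like abundance in 27, 16 higher and 11 lower, of which 16 also passed the rank test, 20 the set test on signed z and 14 both. Counts adjusted over the list alone equalled those over all genes wherever no other count is given. The adjusted p of 0.000507 is the smallest that the 10000 random lists allow. Because only group means and the authors' test were at hand, the table gives no standard deviation or standard error for any gene.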

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

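The limma fits on recovered reads, with their settings, and the set test on signed z were chosen after seeing the data, and the other alternatives before. Requiring at least a 2-fold change left 2039 genes, 1114 higher and 925 lower, in place of 4707. The count was 3548 at an adjusted p under 0.01 and 5441 at one under 0.1, and 4873 and 4399 with the adjustment redone over genes with a mean of at least 10 and of at least 100. Centring on the median log2 change of abundant genes, 0.01, leaves the authors' p-values as they are and so tests nothing about the calls. Of 27 lists whose median stood apart, 16 passed the rank test, which added none. The set test on signed z passed 20 of the 27 and added V(D)J recombination, integrins and the erythroid and platelet list, and 14 lists passed all 3 tests. With the mean in place of the median 23 lists stood apart. The lists for E and Id proteins, T lineage transcription factors, granulocytes and monocytes, cell cycle and sex-linked genes no longer did, V(D)J recombination and the erythroid and platelet list newly did, and the Gimap list reversed, to 0.28 from -0.75, its members lying on both sides of 0. For the 227 named genes, 406 of 413 values with the adjustment limited by mean kept their call and the other 7 newly passed, those of Epcam, Hoxa3 and Tnfrsf1a among them. This redoes the adjustment on the same p-values. The called genes among them were picked for small adjusted p or large change, so their calls could hardly be lost. Of 300 list counts 262 were within 1.5 times the main count. Over the 3136 genes with recovered reads limma called 710; leaving out 1 library gave 468 to 558, with 468 both without the control library of size factor 1.02 and without the dKO library of size factor 1.08. Genes lower numbered 252 and, with 1 library left out, 111 to 225; they were 111, 112 and 138 without the control libraries of size factor 1.02, 0.952 and 0.823. Genes higher numbered 458 and then 295 to 403, with 295 without the dKO library of size factor 1.08. The set of genes with recovered reads favours those higher in dKO, as given below. No paired analysis was possible because the table gives group means and the recovered libraries carry no replicate number. For the same reason the alternatives set out beforehand for counts per library were not run: another count test, other size factors, a low count filter, the replicate block and labelled libraries left out. Of genes with a mean under 10, 1.26% were called, and whether reads, molecules or the spread between libraries set that limit was not tested.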

Other observations

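Of the tests below, those of the reporter, of the spread of the interferon genes and of the single-library explanations for these genes as given here were chosen after results were seen; the tests of the neighbours, of the flanking segments and of single libraries behind low-abundance calls were written before.

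Gt(ROSA)26Sor, the transcript of the Rosa26 locus, fell from 379 to 17.2 in the authors' deposited table, a log2 change of -4.46. Without the dKO library of size factor 1.16 the recovered dKO mean was 8.98. That library was the highest of the dKO group, so leaving it out could only deepen the fall. This does not show whether the fall rested on a single library. The gene was chosen after its value was seen, and that change lies at percentile 0.223 of genes with a mean of at least 100. Lower expression of the whole neighbourhood is argued against by its 10 nearest tested genes, whose median log2 change was 0.12, ranging from -0.12 to 0.43 with none called at the authors' adjusted p of 0.05 and 0 at an unadjusted p under 0.05. A candidate explanation is a YFP reporter inserted at this locus in the dKO animals, whose gate used YFP, although the labels do not say where the reporter lies and regulation of the gene by E proteins stays open, untested. Strain differences in segments flanking Tcf3, Tcf12, Il7r and Gt(ROSA)26Sor were argued against as a wide source of calls: 25.5% of 200 neighbours were called against 29.1% of 15891 other genes, a ratio of 0.877 (Fisher's exact test, 2-sided, p = 0.308).

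The interferon-stimulated genes had large folds and weak p-values. The standard error implied by fold and p was 4.09 times that of random lists of like abundance (median 0.636 against 0.156, 27 members), which restates those folds and p-values and leaves a wide spread between libraries untested over the list. Recovered normalised counts of Mx2 were 45.9, 69.3 and 36.4 in control and 125, 403 and 290 in dKO, those of Ifi44 3.90, 26.3 and 6.07 against 27.7, 219 and 92.5, and in both genes the same dKO library was lowest. Mx2 was called higher and Ifi44 was not called. For the list member Gbp3 only dKO reads were recovered, 215, 453 and 437, with the same library lowest. Gbp3 had means of 403 in control and 369 in dKO and was not called in the authors' deposited table. For Mx2 and Ifi44 a single library as the cause is argued against, since the median log2 ratio was 2.18 without the dKO library of the largest mean share over both genes and 2.58 without the control library of the smallest. That bound had been written for the whole list, but only 2 of its 28 members had reads recovered in both groups, so a single dKO library cannot be excluded for the others, and a difference in genotype, gate or exposure to interferon stays open.

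Calls among genes of low abundance could rest on the reads of a single library. In 0% of the 759 called genes with reads recovered in both groups did 1 library hold 80% or more of the higher group's reads. These genes had already passed a test that weighs the spread between libraries, so few of that kind could remain. The explanation is therefore not excluded. Over 3136 genes with recovered reads limma called 710, 458 higher and 252 lower in dKO. The authors' test called 717 of them, with 645 called by both in the same direction and 0 in opposite directions. Values between 100 and 500 were recovered more often in dKO (77.6%) than in control (18.7%), so this set favours genes higher in dKO. Its balance of directions is therefore not that of all tested genes. The counts per direction moved with single libraries: without the control library of size factor 1.02 limma called 357 higher and 111 lower, and without the dKO library of size factor 1.08 it called 295 higher and 173 lower. Of the 10 splits of the 6 libraries into groups of 3, 1 called as many genes, the real one with 710, and the highest of the others called 0; so few splits cannot give a share under 0.05.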
